A study of Xenopus laevis with 17 samples.

How the data were processed

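RNA sequencing was carried out on animal caps of the frog Xenopus laevis, the ectoderm cut from the top of an early embryo, which forms epidermis when cultured alone. Per the labels' protocols, caps were dissected at stage 10, 20 caps were used per condition, and inducible proteins fused to the human glucocorticoid receptor were switched on with 20 µM dexamethasone at mid-stage 11. Harvest was 9 h later at 22 °C, which the labels equate with stage 18. All RNA libraries came from caps given Multicilin, a coiled-coil protein that switches ectoderm cells to the multiciliated fate. Per the labels, poly-A RNA was made into non-stranded libraries, so reads from a gene and from an overlapping antisense gene cannot be told apart.

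The 9 RNA libraries formed 4 groups. The control group (Multicilin alone, n = 3) was re-used from an earlier study of the same laboratory, per the labels. The new groups received Multicilin together with Cas9 protein and a guide RNA against foxj1 (n = 2), Cas9 protein and a guide RNA against foxn4 (n = 2), or a foxn4 morpholino, an antisense oligonucleotide (n = 2). Every control library belonged to the earlier study and every perturbed library to the new one, so study and group cannot be told apart in any comparison with the control. The labels do not say that replicates came from separate clutches, so the p-values measure only the spread between these samples, which may be technical. A further 2 libraries were chromatin immunoprecipitation (ChIP-seq) of Foxn4 fused to GFP and the glucocorticoid receptor, given alone (n = 1) or with Multicilin (n = 1). The 6 re-used ChIP input libraries were not analysed here.

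Per the file headers, the authors' RNA files were written by eXpress, 1 file per library, and hold an estimated count per gene model in which reads that match several models are shared out. Per the file headers, the same files also hold a count of uniquely matching reads, a count of all matching reads and an estimated count corrected for effective length. The reads were matched to the Mayball gene models, per the series' design text. STAR, eXpress, DESeq, Bowtie2 and HOMER were used, per the submitters' processing notes, and their versions and settings for the RNA files are not given in the sources used here. The authors' deposited comparison tables hold, per the file headers, signal columns of mean normalized counts for each group, a fold ratio, its log2 and a p-value with its adjusted value. A check against the count files showed that the deposited log2 values run as control over perturbed. In the deposited table for Foxj1 the mean over all libraries gave the perturbed group a weight of 0.286, as 2 of 7 libraries would, whereas the other 2 tables gave 0.4, as 2 of 5 would. The Foxj1 table thus rests on more control libraries than the 3 analysed here.

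Per the file headers, the authors called peaks in each ChIP library alone with HOMER, in its setting for transcription factors, at a false discovery rate of 0.001. Each peak also needed 4 times the tags of the input and 4 times those of the surrounding 10000 bp. Both lists used the same input, a re-used library of Myb with Multicilin. The peak files hold, per the file headers, a tag count, a signal of tags scaled to a common library size, a score, fold values over input and over the local region, and a p-value for each. These are the authors' values and were used only to describe peaks within a list. The build was the X. laevis version 7.1 scaffold assembly, per the series' design text, and all coordinates are 1-based positions on its scaffolds.

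Each file listed 24383 gene models with 13473 distinct symbols, of which 7888 had 2 or more models. X. laevis carries paired copies of many genes from a past genome duplication, and reads shared by such copies make the split between them uncertain. The names carry scaffold positions, which were used to join models to peaks. Models without a symbol, 519 in all, held between 1.7 and 2.43% of the counts. Estimated counts per library ranged from 8265823 to 22041340, and uniquely matching reads amounted to between 62.7 and 69.1% of them. Replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom from 13.0 to 131.7, so none was treated as the same library.

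Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter over the 4 groups and the quasi-likelihood test. All 9 libraries entered one fit, with group as the only term and 5 residual degrees of freedom, and 19058 models were tested. The biological coefficient of variation was 0.31. A model was called at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of genes come from this test unless another tool is named. Log2 fold changes are given with standard errors, and levels are CPM with the standard deviation between libraries. Where a group was at 0, the fold is a lower bound against a floor of 3 counts over that group. Where a group held 1 to 3 counts, the ratio of levels is given with its 95% Poisson interval. Such intervals cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

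On simulated counts for the same 19058 models, the test of Foxj1 CRISPR against the control recovered 0, 4.5 and 71.2% of changes of 1.5, 2 and 4 times. The test of Foxn4 CRISPR against Foxj1 CRISPR recovered 0, 0 and 51.5%. Each simulation gave 4 false calls. Only 67, 67 and 66 models were changed by these folds in each, and 54 and 38 models were called in all. Far more were called against the control in the data, which makes the adjusted threshold less strict. The shares recovered therefore do not give the power of the comparisons with the control.

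The 14 gene lists, the rule for naming genes, the comparisons and most alternatives were fixed before the data were examined. Lists were matched by symbol and every tested model counted as a member. The lists covered multiciliated cell regulators, centriole assembly, axonemal motility, intraflagellar transport, the cell cycle, Notch, p53, immediate-early and stress genes, innate immunity, and markers of ionocytes, secretory cells, epidermis, neural tissue and mesoderm or endoderm. Each list was tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, adjusted over the 14 lists of a comparison, and again with a correlation estimated from the libraries. No list in any of the 5 comparisons passed with an estimated correlation, whether all libraries or all but control replicate 2 were used. Estimated correlations reached 0.698 for the motility list and 0.663 for intraflagellar transport, and without control replicate 2 they were at most 0.344 and 0.142.

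Genes are named by 3 fixed criteria. FOXJ1 and FOXN4 are always given, and MCIDAS, the symbol of Multicilin, was added after its values were seen, as were FOXI1 and HES2 beside peaks. In each list with at least 3 called members, the up to 2 largest risers and 2 largest fallers are named. The 5 largest rises and 5 largest falls are taken among called genes with a symbol and a mean of at least 5 CPM. Where a symbol has several models, the model with the larger change is given. Some results that these criteria select are not reported here. HES5 had 11 tested models, FOXI1, OTX2 and TUBB2B had 6, and CA4, HES1, FCGBP and IFIT5 had 5. CDH1, KLF2, KRT12, KRT18, KRT19, SNAI2, DLL1, KLF5, JUN, PAQR5, ANK3 and BMP7 had 4, and the remaining named symbols had between 1 and 3.

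Comparisons that share the control libraries share their chance deviations. For these, 20 simulations of unchanged groups against the same controls gave the value expected from sharing the controls alone. They drew each gene independently and held no difference between studies. The overlap expected of independent lists was computed as well. The 3 controls cannot be split into parts of at least 2 libraries each. Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp, with exact (Clopper-Pearson) 95% binomial intervals. A model counted as having a peak when a peak centre lay within 1000 bp of its start. Called and uncalled models were compared over 10 strata of mean expression by a pooled (Mantel-Haenszel) odds ratio, in a family of 42 tests with Benjamini-Hochberg adjustment. Lists were compared with 10000 random lists matched on expression. The comparisons of peaks with gene starts were chosen after the data were seen, whereas the numbers of peaks and their overlap were planned.

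Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors, no filter and a stricter filter, 3 other count columns, and counts summed per symbol. Others were a fit of only the groups compared, a replicate block, a robust fit, a minimum fold change and leaving out each library in turn. Shared peaks were also computed at 4 other settings. Thinning of all libraries to the shallowest, a block over the CRISPR libraries alone, the estimated correlation without control replicate 2 and the peak windows were added later. No batch label was given beyond the re-use of the controls.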

Results

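The study asked what Foxn4 and Foxj1 contribute to multiciliated cells, which move fluid over the embryonic skin with many motile cilia. Foxj1 is a forkhead transcription factor known for switching on genes of motile cilia, and Foxn4 is a forkhead factor best known from retina and spinal cord. RNA was sequenced from frog animal caps in which Multicilin drove the multiciliated fate, in 3 re-used control libraries and in 2 libraries each of Foxj1 CRISPR, Foxn4 CRISPR and Foxn4 morpholino. The control libraries held 19209914, 19367416 and 22041340 estimated counts. The Foxj1 CRISPR libraries held 12279405 and 12147613, the Foxn4 CRISPR libraries 8265823 and 12402135, and the morpholino libraries 8570033 and 16250144. The 100 most abundant models took between 32.1 and 32.5% of the counts in the controls and between 23.6 and 28.7% in the other groups.

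The first principal component, with 53.4% of the variance, separated the controls from all perturbed libraries, and the second, with 18.4%, separated the morpholino libraries from the rest. Control replicate 2 had a lower level of genes of the multiciliated program than the other controls. FOXN4 on scaffold 44061 stood at 79.0 CPM in it and at 388 and 511 CPM in the others, and the median of the motility list lay at -0.55, against 0.13 and 0.31 on the log2 scale. Values below are means ± SD in CPM and log2 fold changes ± standard error, with n = 3 for the control and n = 2 for every other group.

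**Figure D1:**
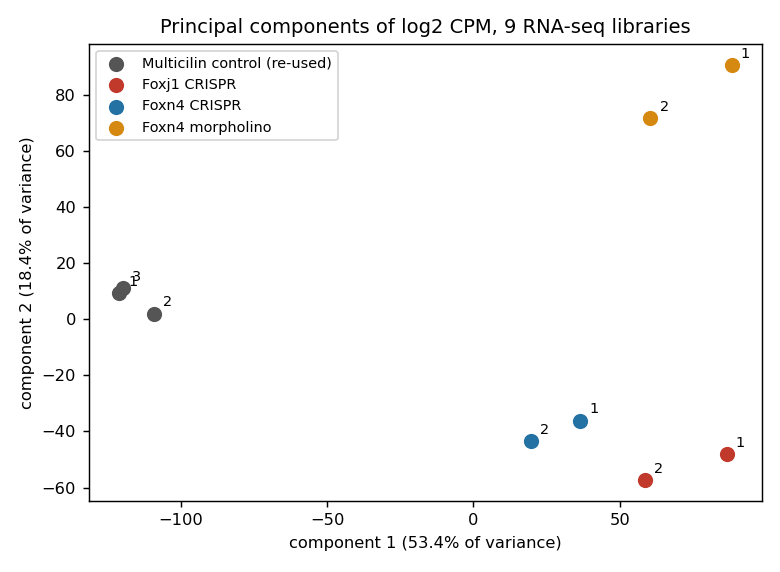
Principal components of log2 CPM for the 9 RNA libraries, with component 1 (53.4% of the variance) on the horizontal axis and component 2 (18.4%) on the vertical axis; each point is a library, coloured by group and numbered by replicate. The 3 controls lie between -121 and -109.2 on component 1, and the perturbed libraries between 19.5 and 88.3.

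The targeted genes themselves were measured first. FOXJ1 had 3 tested models, at positions 620223 to 626121 of scaffold 71264, 1172378 to 1178192 of scaffold 106323 and 2905232 to 2912271 of scaffold 23403 of the version 7.1 assembly. In the Foxj1 CRISPR caps they stood at 1060 ± 14.3, 670 ± 62.8 and 368 ± 17.3 CPM, against 732 ± 152, 611 ± 130 and 307 ± 143 in the control, with adjusted p = 0.0906, 0.695 and 0.587. FOXN4 had 2 tested models, at 1820555 to 1834747 of scaffold 44061 and 1564919 to 1577883 of scaffold 143664. They stood at 367 ± 18.4 and 217 ± 2.27 CPM in the Foxn4 CRISPR caps and at 475 ± 43.4 and 489 ± 35.2 with the morpholino, against 326 ± 222 and 199 ± 131 in the control. Their adjusted p was 0.844 and 0.881 with CRISPR and 0.438 and 0.0641 with the morpholino. Neither a small deletion nor a morpholino need change the amount of the target's RNA, so these levels do not check the labels. MCIDAS, the gene of Multicilin, rose on scaffold 337825 in the Foxj1 CRISPR caps (log2 1.65 ± 0.51, adjusted p = 0.027) and with the morpholino (1.63 ± 0.51, adjusted p = 0.0259). With Foxn4 CRISPR the same MCIDAS model stood at 1.32 ± 0.51 (adjusted p = 0.0868). Injected and endogenous Multicilin RNA were not told apart. The MCIDAS calls ended without control replicate 1 (1.72 and 1.66) and without either replicate of the perturbed group (1.58 and 1.71 for Foxj1 CRISPR, 1.37 and 1.83 for the morpholino).

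Caps with Foxj1 CRISPR had far less RNA of the genes that build and move cilia than the Multicilin control. Of the 117 tested models of axonemal dyneins and other motility proteins, 112 fell, 0 rose and 5 were not called. Genes that regulate or start the multiciliated program mostly stayed uncalled, and genes of the Notch pathway and the cell cycle were more often higher than lower. DNAH6, a dynein heavy chain, fell from 1170 ± 233 to 28.6 ± 35.0 CPM, and EFHB, a protein of ciliary microtubules, from 199 ± 54.3 to 6.05 ± 5.49 CPM. Their log2 fold changes were -5.35 ± 0.92 (adjusted p = 0.00164) and -5.04 ± 0.6 (adjusted p = 0.000312).

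Adjusted over the list alone, 114 motility models fell and 0 rose. The median was -2.13 and the camera adjusted p was 4.33e-41, with an adjusted p = 0.359 with an estimated correlation. Intraflagellar transport carries building material along the cilium. Of 56 models of this list, 48 fell, 2 rose and 6 were not called, and adjusted over the list alone 50 fell and 2 rose (median -1.45, camera adjusted p = 5.1e-13, adjusted p = 0.438 with an estimated correlation). KIFAP3, part of the kinesin-2 motor, fell (log2 -4.39 ± 0.67), as did IFT74 (-3.33 ± 0.43), whereas the chaperonin-like BBS10 (1.23 ± 0.37) and MKKS (1.05 ± 0.32) rose. Without Foxj1 CRISPR replicate 1, 23 members of this list were called in place of 50.

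Of 57 models of centriole assembly, 15 fell, 4 rose and 38 were not called, and adjusted over the list alone the split was the same at 15 and 4. The median was -0.53 and the camera adjusted p was 0.048, with an adjusted p = 0.737 with an estimated correlation. CCDC78, which takes part in making many centrioles at once, fell (log2 -4.28 ± 0.57), as did TUBD1, delta-tubulin (-2.61 ± 0.34). SASS6, of the centriole cartwheel, rose (1.43 ± 0.33), as did CEP192 (1.15 ± 0.36). The number of called members was 39 without control replicate 2, 12 without control replicate 3, and 5 and 8 without Foxj1 CRISPR replicates 1 and 2. Of 30 models of multiciliated cell regulators, 2 rose, 6 fell and 22 were not called, and adjusted over the list alone 2 rose and 5 fell. Their median was 0.1 while the mean was -0.39 (camera adjusted p = 0.69, adjusted p = 0.828 with an estimated correlation). TFDP1, the partner of E2F factors (log2 1.46 ± 0.23), and MYB (1.14 ± 0.34) rose, and RFX3, a regulator of cilia genes (-3.21 ± 0.64), and MYCBP2 (-2.68 ± 0.46) fell. MYCBP2 was listed by symbol, its role in these cells unchecked.

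Of 88 models of the cell cycle, 34 rose, 7 fell and 47 were not called, and adjusted over the list alone 35 rose and 7 fell. The median was 0.71 (camera adjusted p = 0.000272, adjusted p = 0.359 with an estimated correlation). CCNE2, a cyclin of the entry into DNA replication (log2 3.79 ± 1.06), and E2F3 (2.31 ± 0.34) rose, while CCNA1 (-5.66 ± 1.38) and the phosphatase CDC25A (-3.81 ± 0.51) fell. Without Foxj1 CRISPR replicate 1, 20 members were called. Of 49 Notch pathway models, 23 rose, 1 fell and 25 were not called, and adjusted over the list alone 25 rose and 3 fell (median 1.55, camera adjusted p = 1.97e-05, adjusted p = 0.317 with an estimated correlation). HES2, a repressor of the hairy family, rose from 0.691 ± 0.562 to 46.5 ± 5.88 CPM (log2 6.08 ± 0.52, adjusted p = 9.58e-05), and a model of HES5 rose as well (3.78 ± 1.0). RBPJ, the DNA-binding partner of Notch, fell (-1.02 ± 0.29). When reads matching several models were counted at each, its value was 0.62. The Notch list had 13 and 15 called members without Foxj1 CRISPR replicates 1 and 2.

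Of 39 models of the p53 and DNA damage list, 14 rose, 7 fell and 18 were not called, and 14 and 8 adjusted over the list alone (median 0.49, camera adjusted p = 0.108, adjusted p = 0.737 with an estimated correlation). SESN1 (log2 2.81 ± 0.49) and AEN (2.59 ± 0.48) rose and DDB2 fell (-2.63 ± 0.92). GADD45B was higher in the control by a ratio of 54.8 (95% interval 9.83 to 2160). Of 55 immediate-early and stress models, 11 rose, 8 fell and 36 were not called, and 11 and 8 adjusted over the list alone (median -0.05 but mean 0.11, camera adjusted p = 0.554, adjusted p = 0.737 with an estimated correlation). KLF2 (3.73 ± 0.37) and SOCS3 (2.99 ± 0.67) rose, and HSP90AA1 (-2.67 ± 0.93) and JUNB (-2.28 ± 0.52) fell. The fall of HSP90AA1 rested on control replicates 1 and 3, at 166 and 72.3 CPM, since control replicate 2, at 7.78 CPM, lay below both Foxj1 CRISPR libraries. Of 37 innate immune models, 9 rose, 6 fell and 22 were not called, and 9 and 6 adjusted over the list alone (median 0.07, camera adjusted p = 0.559, adjusted p = 0.737 with an estimated correlation). IRF7 rose (4.47 ± 0.7) and TNFAIP3 fell (-3.04 ± 0.79). Without Foxj1 CRISPR replicate 1 these lists had 12, 5 and 5 called members, without replicate 2 the stress and immune lists had 11 and 5, and without control replicates 1 or 3 the immune list had 8.

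Markers of other cell types in the caps moved both ways. Ionocytes, which transport ions and acid, had 9 of 50 models higher, 15 lower and 26 not called, and 9 and 16 adjusted over the list alone (median -0.71, camera adjusted p = 0.303, adjusted p = 0.737 with an estimated correlation). A model with the symbol FOXI1, that of the ionocyte master regulator, rose from 0.395 ± 0.151 to 27.7 ± 0.0247 CPM (log2 6.1 ± 0.4). Models with this symbol lie on several scaffolds, and on scaffold 1168 at both 1510409 and 1527034. Which of them encodes the ionocyte regulator was not determined. A model of CA4, a carbonic anhydrase, was at least 15.5-fold higher. The anion exchanger SLC26A4 (-5.09 ± 1.22) and CA2 (-4.43 ± 0.85) fell. Of 29 models of secretory cell markers, 5 rose, 11 fell and 13 were not called, and 7 and 12 adjusted over the list alone (median -0.87, camera adjusted p = 0.27, adjusted p = 0.737 with an estimated correlation). MUC2 (3.56 ± 1.06) and TFF2 (3.09 ± 0.62) rose and CAPN9 fell (-3.9 ± 0.54), while AGR3 was higher in the control by a ratio of 36.8 (6.6 to 1450). Without Foxj1 CRISPR replicate 1, 12 ionocyte and 9 secretory models were called, and 7 secretory models without replicate 2.

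Of 73 epidermal and basal cell models, 10 rose, 15 fell and 48 were not called, with 10 and 15 adjusted over the list alone (median -0.19, camera adjusted p = 0.507, adjusted p = 0.737 with an estimated correlation). KLF4 (log2 2.29 ± 0.27) and CDH1, E-cadherin (1.85 ± 0.36), rose, and TP63, the basal cell factor (-5.89 ± 1.1), and KRT19 (-2.87 ± 0.66) fell. Of 58 neural and neural crest models, 22 rose, 11 fell and 25 were not called, with 24 and 11 adjusted over the list alone (median 0.86, camera adjusted p = 0.0286, adjusted p = 0.438 with an estimated correlation). POU3F2 (5.23 ± 0.64) and OTX2 (4.73 ± 0.49) rose, SNAI2 was higher in the control by a ratio of 125 (22.4 to 4930) and a model of TUBB2B at least 2.68-fold, with a value of 3.1 in the opposite direction when multiply matching reads were counted at each model. Of 32 mesoderm and endoderm models, 11 rose, 4 fell and 17 were not called, with 11 and 4 adjusted over the list alone (median 1.19, or 0.87 with members at their bound, camera adjusted p = 0.0189, adjusted p = 0.362 with an estimated correlation). GSC, goosecoid, was at least 30.4-fold higher and MYF5 higher by a ratio of 44.7 (8.03 to 1770). GATA1 (-3.4 ± 0.88) and ACTA1 (-5.53 ± 1.18) fell, with ACTA1 at 0.22 under the same change of counting. The neural list had a camera adjusted p of 0.112 without control replicate 2, and the epidermal list 16 called members without Foxj1 CRISPR replicate 1.

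Among genes above 5 CPM the largest rises were those of ADA, adenosine deaminase, with a ratio of 1300 (360 to 10800), FCRL3 (log2 8.23 ± 0.5), NT5E with a ratio of 346 (95.7 to 2850), NINJ2 (7.99 ± 0.51) and the receptor GFRA1 (7.15 ± 0.64). The largest falls by group mean were those of AGTR2, at least 162-fold, MYOT, at least 115-fold, CAV1, at least 77.7-fold, and the homeobox gene HOXA2, with a ratio of 496 (89.0 to 19600). The falls of AGTR2 and MYOT rested on control replicates 2 and 3, with 16.8 and 36.4 CPM of AGTR2 and 13.4 and 24.2 CPM of MYOT, against 0.127 CPM of each in control replicate 1. With edgeR's quasi-likelihood test, 3768 models rose and 3944 fell, and 9526 had an unadjusted p under 0.05. Calls numbered 3431 without Foxj1 CRISPR replicate 1 and 4952 without replicate 2. Of the 61 named models called, 21 and 15 lost their call without these libraries, AGTR2 and MYOT in both cases, 5 without control replicate 1, 5 without control replicate 3 and 1 or 2 without any other library. All of these values set new libraries against controls of an earlier study.

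**Figure D2:**
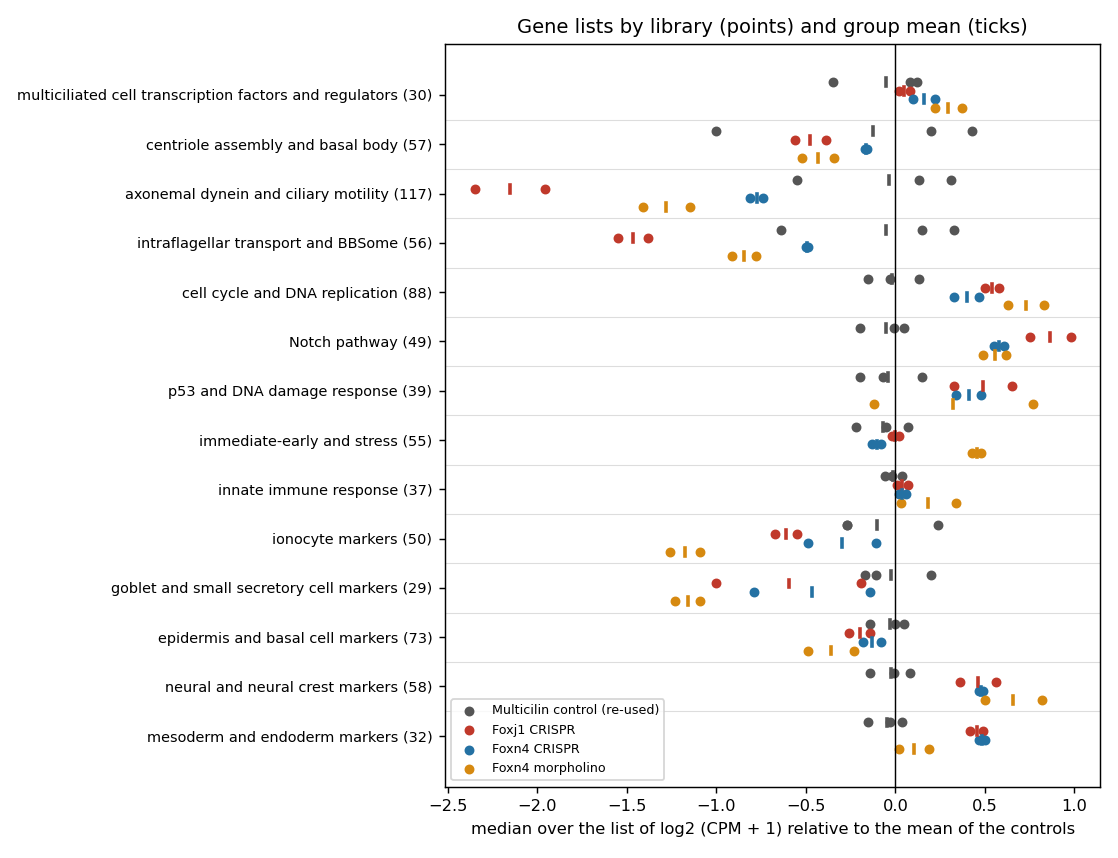
Medians over each gene list of log2 (CPM + 1) relative to the mean of the controls, on the horizontal axis, for 14 lists with the number of tested models in brackets; points are libraries, coloured by group, and ticks are group means. The motility list lies lowest in the Foxj1 CRISPR libraries, with fitted medians of -2.13 for Foxj1 CRISPR, -1.29 for the morpholino and -0.77 for Foxn4 CRISPR.

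Foxn4 CRISPR caps were set against the same controls. Of the 117 models of cilium motility, 33 were lower than in the control and 84 not called, with a median of -0.77 on the log2 scale, and genes of centriole assembly were mostly not called. Neural, Notch and cell cycle genes were more often higher than lower. TEKT3, a tektin that lines ciliary microtubules, fell from 266 ± 87.6 to 24.1 ± 6.43 CPM (log2 -3.46 ± 0.56, adjusted p = 0.00276), and TTC29 fell from 172 ± 54.1 to 51.3 ± 18.4 CPM (-1.74 ± 0.39, adjusted p = 0.0119).

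None of the motility models rose (0 by edgeR), and adjusted over the list alone 35 fell and 0 rose. The camera adjusted p was 9.38e-10, with an adjusted p = 0.857 with an estimated correlation. The number called rested on single libraries. It was 11, 78 and 15 without control replicates 1, 2 and 3, and 3 without either Foxn4 CRISPR replicate. Of 56 transport models, 7 fell, 1 rose and 48 were not called, and adjusted over the list alone 1 fell and 0 rose (median -0.51, camera adjusted p = 0.00197, adjusted p = 0.888 with an estimated correlation). KIFAP3 (-2.27 ± 0.58) and ARL3 (-1.55 ± 0.31) fell and BBS10 rose (1.26 ± 0.37). This list had 2, 28 and 1 called members without control replicates 1, 2 and 3, 4 without either Foxj1 CRISPR replicate and 0 without either Foxn4 CRISPR replicate.

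Of 57 centriole models, 2 rose, 2 fell and 53 were not called, with 1 and 1 adjusted over the list alone (median -0.13, camera adjusted p = 0.723, adjusted p = 0.976 with an estimated correlation). CETN2, a centrin (log2 1.25 ± 0.24), and SASS6 (1.21 ± 0.33) rose and CEP164, of the basal body's distal appendages, fell (-2.08 ± 0.41). The number called was 2 without control replicate 1, 16 without control replicate 2, and 0 without either Foxn4 CRISPR replicate. Of 30 regulator models, 3 rose, 2 fell and 25 were not called, with 2 and 2 adjusted over the list alone (median 0.17 but mean -0.07, camera adjusted p = 0.766, adjusted p = 0.976 with an estimated correlation). TFDP1 (1.39 ± 0.23) rose and MYCBP2 fell (-2.02 ± 0.4). Here 3 members were called without either Foxj1 CRISPR replicate or Foxn4 CRISPR replicate 1, and 1 without Foxn4 CRISPR replicate 2.

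Of 88 cell cycle models, 18 rose, 4 fell and 66 were not called, with 18 and 5 adjusted over the list alone (median 0.53, camera adjusted p = 0.0124, adjusted p = 0.616 with an estimated correlation). CCNE2 (log2 4.05 ± 1.06) and the replication helicase subunit MCM4 (2.17 ± 0.33) rose, CCNA1 fell (-6.14 ± 1.43), and a model of CCNB1 was higher in the control by a ratio of 6.67 (2.28 to 32.4). Called members numbered 14 and 34 without control replicates 1 and 2, and 5 and 8 without Foxn4 CRISPR replicates 1 and 2. Of 49 Notch models, 8 rose, 1 fell and 40 were not called, with 8 and 1 adjusted over the list alone (median 1.1, camera adjusted p = 0.00181, adjusted p = 0.605 with an estimated correlation). DLL1, a Notch ligand (2.75 ± 0.53), and NRARP (2.19 ± 0.43) rose and NUMB, a Notch inhibitor, fell (-1.02 ± 0.27). Called members numbered 14 without control replicate 3 or morpholino replicate 2, and 5 and 2 without Foxn4 CRISPR replicates 1 and 2.

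Of 39 p53 models, 10 rose, 1 fell and 28 were not called, with 11 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 0.0578, adjusted p = 0.857 with an estimated correlation). SESN1 (log2 2.48 ± 0.49) rose and GADD45B fell (-2.78 ± 0.87). Of 55 stress models, 3 rose, 3 fell and 49 were not called, with 3 and 1 adjusted over the list alone (median -0.09 with camera direction up, adjusted p = 0.981, adjusted p = 0.985 with an estimated correlation). SOCS3 (2.87 ± 0.68) and KLF2 (2.71 ± 0.36) rose, and KLF6 (-1.85 ± 0.46) and JUNB (-1.46 ± 0.42) fell. Of 37 immune models, 5 rose, 3 fell and 29 were not called, with 5 and 3 adjusted over the list alone (median 0.17, camera adjusted p = 0.545, adjusted p = 0.888 with an estimated correlation). IRF7 (3.34 ± 0.71) and IRF1 (3.19 ± 0.59) rose, and TNFAIP3 (-2.74 ± 0.78) fell. Without Foxn4 CRISPR replicate 1 the 3 lists had 2, 1 and 3 called members, and without replicate 2 they had 3, 3 and 2. The p53 list had 4 without control replicate 3 and 7 without either Foxj1 CRISPR replicate, and the stress list 12 and 10 without control replicates 2 and 3.

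Of 50 ionocyte models, 9 rose, 4 fell and 37 were not called, with 10 and 4 adjusted over the list alone (median -0.28 but mean 0.11, camera adjusted p = 0.821, adjusted p = 0.976 with an estimated correlation). A CA4 model was at least 26.7-fold higher and FOXI1 rose (log2 3.79 ± 0.4), while another CA4 model (-2.36 ± 0.58) and the proton pump subunit ATP6V1A (-1.47 ± 0.26) fell. Of 29 secretory models, 4 rose, 7 fell and 18 were not called, with 5 and 9 adjusted over the list alone (median -0.29, camera adjusted p = 0.402, adjusted p = 0.888 with an estimated correlation). TFF2 (4.07 ± 0.61) and FOXA2 (3.3 ± 0.74) rose. ITLN1, intelectin of goblet cells, fell from 1470 ± 795 to 223 ± 54.3 CPM (-2.72 ± 0.43), and AGR3 was higher in the control by a ratio of 14 (3.88 to 116). Without Foxn4 CRISPR replicate 1, 8 ionocyte and 4 secretory models were called, and 6 secretory models without replicate 2.

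Of 73 epidermal models, 9 rose, 11 fell and 53 were not called, with 9 and 12 adjusted over the list alone (median -0.14, camera adjusted p = 0.723, adjusted p = 0.976 with an estimated correlation). KLF4 (log2 2.59 ± 0.27) and KRT12 (1.75 ± 0.51) rose, and TP63 (-3.3 ± 0.92) and KRT19 (-2.61 ± 0.65) fell. KRT12 stood at -1.04 on uniquely matching reads and at -1.01 with multiply matching reads counted at each model. Of 58 neural models, 19 rose, 7 fell and 32 were not called, with 22 and 7 adjusted over the list alone (median 0.83, camera adjusted p = 0.0107, adjusted p = 0.605 with an estimated correlation). POU3F2 (4.84 ± 0.65) and OTX2 (4.23 ± 0.8) rose, and SNAI2 (-4.0 ± 0.97) and FOXD3, a neural crest factor (-3.23 ± 0.39), fell. Of 32 mesoderm and endoderm models, 8 rose, 3 fell and 21 were not called, with 11 and 3 adjusted over the list alone (median 1.4, camera adjusted p = 0.0124, adjusted p = 0.605 with an estimated correlation). GSC was at least 81.7-fold higher, MYF5 higher by a ratio of 45.7 (8.2 to 1800), and ACTA1 (-5.03 ± 1.27) and TAL1 (-1.03 ± 0.21) fell. Without Foxn4 CRISPR replicate 1 the 3 lists had 6, 15 and 2 called members, and without replicate 2 they had 5, 16 and 3.

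The largest rises were those of ADA, with a ratio of 1220 (337 to 10100), the homeobox gene GSX1, with a ratio of 1430 (256 to 56300), NINJ2 (log2 8.43 ± 0.51), NT5E, with a ratio of 377 and an upper 95% limit of 3110, and FCRL3 (8.04 ± 0.5). GSX1 rested on 1 library, with 56.0 CPM in Foxn4 CRISPR replicate 2 and 0 in replicate 1. The largest falls were those of AGTR2, at least 124-fold, MYOT, at least 87.6-fold, CAV1, at least 59.3-fold, and BTBD17, with a ratio of 530 (147 to 4370). AGTR2 and MYOT stood at 0.127 CPM in control replicate 1, so their falls rested on the other 2 controls. In all, 2393 models rose and 2031 fell, and 7291 had an unadjusted p under 0.05. Calls numbered 1213 and 1483 without Foxn4 CRISPR replicates 1 and 2. Of the 55 named models called, 31 lost their call without either library, 7, 4 and 6 without control replicates 1, 2 and 3, and 2 or 3 without any other single library.

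In caps with the Foxn4 morpholino, 92 of 117 motility models were lower than in the control. Markers of ionocytes, secretory cells and epidermis were more often lower than higher, and cell cycle, Notch and neural genes more often higher. TEKT3 fell from 266 ± 87.6 to 5.9 ± 5.15 CPM (log2 -5.45 ± 0.63, adjusted p = 0.000247), and ITLN1 from 1470 ± 795 to 33.4 ± 5.77 CPM (-5.46 ± 0.5, adjusted p = 9.97e-05).

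Of these motility models, 0 rose and 25 were not called, and adjusted over the list alone 101 fell and 0 rose (median -1.29, camera adjusted p = 1.94e-16, adjusted p = 0.468 with an estimated correlation). PIFO, a protein of the ciliary base, fell (log2 -4.09 ± 0.95). Of 56 transport models, 31 fell, 3 rose and 22 were not called, with 35 and 3 adjusted over the list alone (median -0.87, camera adjusted p = 2.14e-05, adjusted p = 0.581 with an estimated correlation). KIFAP3 (-3.34 ± 0.62) and IFT46 (-2.34 ± 0.28) fell, and BBS10 (1.86 ± 0.37) and TTC21B (1.3 ± 0.34) rose. Without morpholino replicate 1, 47 motility and 13 transport models were called, and the transport list had 20 without morpholino replicate 2 and 22 without control replicate 1.

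Of 57 centriole models, 6 rose, 11 fell and 40 were not called, with 4 and 7 adjusted over the list alone (median -0.47, camera adjusted p = 0.12, adjusted p = 0.725 with an estimated correlation). SASS6 (log2 1.46 ± 0.33) and CEP57 (1.37 ± 0.31) rose, and CEP164 (-2.84 ± 0.43) and CCDC78 (-2.11 ± 0.51) fell. The number called was 39 without control replicate 2, 11 without control replicates 1 or 3 or either Foxn4 CRISPR replicate, and 5 and 10 without morpholino replicates 1 and 2. Of 30 regulator models, 7 rose, 4 fell and 19 were not called, with 7 and 4 adjusted over the list alone (median 0.34, camera adjusted p = 0.39, adjusted p = 0.725 with an estimated correlation). SOX9 (2.89 ± 0.49) and MYB (1.58 ± 0.34) rose, and MYCBP2 (-1.7 ± 0.43) and RFX3 (-1.66 ± 0.49) fell, and 3 members were called without morpholino replicate 1.

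Of 88 cell cycle models, 43 rose, 7 fell and 38 were not called, with 44 and 8 adjusted over the list alone (median 0.91, camera adjusted p = 0.000475, adjusted p = 0.459 with an estimated correlation). CCNE2 (log2 3.69 ± 0.28) and MCM4 (2.87 ± 0.33) rose, and CCNA1 (-6.14 ± 1.42) and CDC25A (-4.81 ± 0.54) fell, with 25 members called without morpholino replicate 1. Of 49 Notch models, 20 rose, 2 fell and 27 were not called, with 20 and 2 adjusted over the list alone (median 1.12, camera adjusted p = 0.00803, adjusted p = 0.459 with an estimated correlation). A model of HES5 rose from 1.44 ± 0.712 to 28.5 ± 2.5 CPM (4.3 ± 0.38) and DLL1 rose (3.31 ± 0.52), while HES1 (-1.41 ± 0.32) and RBPJ (-1.11 ± 0.3) fell, RBPJ with 0.05 when multiply matching reads were counted at each model. Of 39 p53 models, 15 rose, 6 fell and 18 were not called, with 15 and 7 adjusted over the list alone (median 0.33, camera adjusted p = 0.39, adjusted p = 0.725 with an estimated correlation). The death receptor FAS (3.12 ± 0.55) and SESN1 (2.59 ± 0.49) rose, and BTG2 fell (-2.67 ± 0.39), while GADD45B was higher in the control by a ratio of 28.0 (7.75 to 231).

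Of 55 stress models, 17 rose, 6 fell and 32 were not called, with 17 and 6 adjusted over the list alone (median 0.61, camera adjusted p = 0.061, adjusted p = 0.459 with an estimated correlation). DDIT3, a factor of the unfolded protein response (log2 5.64 ± 0.8), and KLF2 (2.95 ± 0.36) rose, and KLF6 (-3.53 ± 0.52) and JUNB (-2.47 ± 0.52) fell. Of 37 immune models, 12 rose, 6 fell and 19 were not called, with 13 and 6 adjusted over the list alone (median 0.46, camera adjusted p = 0.307, adjusted p = 0.581 with an estimated correlation). IL1B was higher by a ratio of 123 (22.0 to 4840), and TNFAIP3 (-3.17 ± 0.79) and NFKB2 (-1.45 ± 0.51) fell. The immune list had 11 called members without morpholino replicate 1.

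Of 50 ionocyte models, 9 rose, 26 fell and 15 were not called, with 9 and 26 adjusted over the list alone (median -1.22, camera adjusted p = 0.0184, adjusted p = 0.493 with an estimated correlation). Models of CA4 (log2 7.68 ± 0.56) and FOXI1 (5.49 ± 0.4) rose, another CA4 model was at least 44.2-fold lower, and the proton pump subunit ATP6V1G3 was higher in the control by a ratio of 131 (23.5 to 5170). Of 29 secretory models, 5 rose, 16 fell and 8 were not called, with 6 and 16 adjusted over the list alone (median -1.39, camera adjusted p = 0.0031, adjusted p = 0.459 with an estimated correlation). FOXA2 (4.58 ± 0.7) and FCGBP (3.23 ± 0.88) rose, and CAPN9 (-6.77 ± 0.66) fell beside ITLN1. Of 73 epidermal models, 10 rose, 26 fell and 37 were not called, with 12 and 28 adjusted over the list alone (median -0.31, camera adjusted p = 0.0184, adjusted p = 0.468 with an estimated correlation). KLF4 (2.95 ± 0.27) and CDH1 (2.26 ± 0.36) rose, and TP63 (-6.12 ± 1.13) and KRT18 (-3.86 ± 0.71) fell. The ionocyte list had 23 called members without morpholino replicate 1.

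Of 58 neural models, 31 rose, 9 fell and 18 were not called, with 32 and 11 adjusted over the list alone (median 1.34, camera adjusted p = 0.0206, adjusted p = 0.468 with an estimated correlation). POU3F2 (log2 5.33 ± 0.64) and OTX2 (4.21 ± 0.47) rose, and GBX2 (-6.46 ± 0.49) and SNAI2 (-4.17 ± 0.95) fell, and the camera adjusted p was 0.0665 without control replicate 2. Of 32 mesoderm and endoderm models, 9 rose, 6 fell and 17 were not called, with 9 and 6 adjusted over the list alone (median 0.57, camera adjusted p = 0.414, adjusted p = 0.725 with an estimated correlation). GSC was at least 247-fold and CER1 at least 9.05-fold higher, ACTA1 fell (-5.45 ± 1.28), and T, brachyury, was higher in the control by a ratio of 49.5 (13.7 to 409), with 9 members called without morpholino replicate 1.

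Beside GSC, the largest rises were those of ADA, with a ratio of 1020 (283 to 8440), P2RX7, with a ratio of 635 (176 to 5240), PSAT1, of serine synthesis (log2 8.9 ± 0.79), and NINJ2 (8.5 ± 0.51). The largest falls were those of AGTR2, at least 166-fold, BMP1, at least 157-fold, AVPR1B, at least 118-fold, and MYOT, at least 117-fold, with AGTR2 and MYOT again at 0.127 CPM in control replicate 1. In all, 4553 models rose and 4018 fell, and 10134 had an unadjusted p under 0.05, and 5310 models were called without morpholino replicate 1. Of the 62 named models called, 17 and 5 lost their call without morpholino replicates 1 and 2, 2 without control replicate 1, and 1 or 0 without any other library.

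Foxn4 CRISPR and Foxj1 CRISPR caps belonged to the same new study, so no re-used library stands on either side, although the controls entered the shared fit. Of the 117 motility models, 43 were higher in the Foxn4 CRISPR caps and 0 lower. DNAH6 stood at 562 ± 77.3 CPM against 28.6 ± 35.0 in the Foxj1 CRISPR caps (log2 4.3 ± 0.89, adjusted p = 0.0456), and EFHB, at 6.05 ± 5.49 CPM in the Foxj1 CRISPR caps, was higher as well (4.1 ± 0.59, adjusted p = 0.0166). Of the 276 models called, 272 were higher and 4 lower in the Foxn4 CRISPR caps.

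The other 74 motility models were not called, and adjusted over the list alone 97 were higher and 0 lower (median 1.36, camera adjusted p = 3.41e-79, adjusted p = 0.349 with an estimated correlation). Of 56 transport models, 3 were higher and 53 not called, with 33 and 0 adjusted over the list alone (median 0.93, camera adjusted p = 4.98e-23, adjusted p = 0.378 with an estimated correlation). IFT74 (log2 2.05 ± 0.42) and BBS4, of the complex that sorts ciliary membrane cargo (1.84 ± 0.28), were higher. Of 57 centriole models, 3 were higher and 54 not called, with 3 and 0 adjusted over the list alone (median 0.37, camera adjusted p = 0.000909, adjusted p = 0.794 with an estimated correlation). CCDC78 (3.53 ± 0.57) and FGFR1OP (2.05 ± 0.36) were higher. The motility list had 75 called members without control replicate 2, 21 without Foxj1 CRISPR replicate 2, and 0 without Foxj1 CRISPR replicate 1 or either Foxn4 CRISPR replicate. For transport the numbers were 16 and 6 without control replicates 2 and 3, and 0 without any of the 4 CRISPR libraries. For centrioles they were 5 without control replicate 2, 1 without Foxj1 CRISPR replicate 2 and 0 without the other CRISPR libraries.

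The cell cycle list had 0 members called and a median of -0.22 (camera adjusted p = 0.00131, adjusted p = 0.378 with an estimated correlation), and the Notch list 1 lower and 48 not called with a median of -0.42 (camera adjusted p = 0.00131, adjusted p = 0.378 with an estimated correlation). The ionocyte list had 1 higher, 1 lower and 48 not called, with 1 and 2 adjusted over the list alone (median 0.61, camera adjusted p = 0.00446, adjusted p = 0.544 with an estimated correlation). The p53 list had 1 higher and 38 not called (1 and 0 adjusted over the list alone, median -0.05 but mean 0.1, camera adjusted p = 0.869, adjusted p = 0.977 with an estimated correlation). The regulator, stress, immune, secretory, epidermal, neural and mesoderm lists had 0 called members, and adjusted over the list alone only the neural list had any, 1 higher and 1 lower. Their medians were 0.28, -0.08, 0.1, 0.36, 0.15, 0.01 and -0.27, and the lowest camera adjusted p was 0.215, with 0.545 as the lowest adjusted p with an estimated correlation. The largest differences were those of C1orf227 (log2 5.15 ± 0.81), HEATR4 (4.72 ± 0.67), CCDC17 (4.68 ± 0.73) and CCDC170 (4.55 ± 0.83), followed by DNAH6. Lower were HES2, at 2.31 ± 0.542 CPM against 46.5 ± 5.88 (-4.31 ± 0.56, adjusted p = 0.0166), FOXI1 (-2.31 ± 0.38), LRRC47 (-1.64 ± 0.31) and BMP7, a secreted signal (-1.4 ± 0.25).

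With edgeR, 2165 models had an unadjusted p under 0.05, and DESeq2 called 739, 700 higher and 39 lower. No model was called without Foxj1 CRISPR replicate 1 (0 by edgeR, 1079 at an unadjusted p under 0.05) or without Foxn4 CRISPR replicate 1 (0, with 1610), and 1 without Foxn4 CRISPR replicate 2. Calls numbered 176 without Foxj1 CRISPR replicate 2, 614 without control replicate 2, 705 in a fit of only these 2 groups and 429 with no filter on low counts. All 14 named models called, DNAH6, EFHB and HES2 among them, lost their call without Foxj1 CRISPR replicate 1 or either Foxn4 CRISPR replicate, 5 without Foxj1 CRISPR replicate 2, and up to 3 without a control or morpholino library. Their direction was the same in each of these fits.

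The morpholino and CRISPR were both aimed at Foxn4, and the direct comparison asks where they differ. Among the called markers of ionocytes, secretory cells and epidermis more were lower than higher with the morpholino, and among called stress genes more were higher, though most members of these lists were not called. SLC26A4, an ionocyte anion exchanger, stood at 1.83 ± 0.0498 CPM with the morpholino and 88.9 ± 58.4 with CRISPR (log2 -5.6 ± 0.83, adjusted p = 0.00615). CHAC1, a gene of the stress response to misfolded protein, stood at 63.3 ± 44.6 against 0.298 ± 0.251 CPM (7.56 ± 1.0, adjusted p = 0.0039).

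Of 50 ionocyte models, 4 were higher, 13 lower and 33 not called, with 6 and 19 adjusted over the list alone (median -0.72, camera adjusted p = 3.11e-05, adjusted p = 0.421 with an estimated correlation). Models of CA4 (log2 3.67 ± 0.51) and FOXI1 (2.29 ± 0.36) were higher, and another CA4 model was at least 8.56-fold lower. Of 29 secretory models, 5 were lower, 0 higher and 24 not called, with 6 and 0 adjusted over the list alone (median -0.9, camera adjusted p = 3.11e-05, adjusted p = 0.392 with an estimated correlation). CAPN9 (-4.07 ± 0.63) and AGR2 (-3.99 ± 0.91) were lower. Of 73 epidermal models, 7 were lower, 0 higher and 66 not called, with 14 lower and 2 higher adjusted over the list alone (median -0.3, camera adjusted p = 0.000878, adjusted p = 0.435 with an estimated correlation). KLF5 (-3.24 ± 0.47) and KRT18 (-3.11 ± 0.46) were lower. The ionocyte list had 7 and 4 called members without Foxn4 CRISPR replicates 1 and 2 and 3 and 10 without morpholino replicates 1 and 2. The secretory list had 3, 2 and 1, and the epidermal list 2, 1 and 3, without Foxn4 CRISPR replicates 1 and 2 and morpholino replicate 1, and the epidermal list 16 without control replicate 2.

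Of 55 stress models, 7 were higher, 0 lower and 48 not called, with 9 and 1 adjusted over the list alone (median 0.37, camera adjusted p = 0.00387, adjusted p = 0.392 with an estimated correlation). DDIT3 (log2 3.65 ± 0.83) and JUN (2.94 ± 0.4) were higher. Of 88 cell cycle models, 4 were higher, 1 lower and 83 not called, with 6 and 1 adjusted over the list alone (median 0.37, camera adjusted p = 0.0114, adjusted p = 0.512 with an estimated correlation). CCNA2 was higher (1.69 ± 0.42), a CCNB1 model higher by a ratio of 17.6 (6.01 to 85.2), and CDC25A lower (-2.59 ± 0.5). Of 39 p53 models, 3 were lower, 0 higher and 36 not called, with 5 and 0 adjusted over the list alone (median 0.06 but mean -0.15, camera adjusted p = 0.332, adjusted p = 0.784 with an estimated correlation), CCNG2 (-1.95 ± 0.46) and BTG2 (-1.93 ± 0.4) among them. Of 37 immune models, 3 were higher, 0 lower and 34 not called, with 3 and 0 adjusted over the list alone (median 0.06, camera adjusted p = 0.536, adjusted p = 0.784 with an estimated correlation). IL1B was at least 16.8-fold higher and IFIT5 higher (3.16 ± 0.71). Without Foxn4 CRISPR replicate 1 these 4 lists had 1, 0, 1 and 0 called members, and without replicate 2 they had 0. Without morpholino replicate 1 the stress, cell cycle and p53 lists had 2, 0 and 0, and the immune list had 0 without morpholino replicate 2. Without control replicate 2 the first 3 had 11, 8 and 7, and the cell cycle list had 3 without control replicate 3 and 2 without either Foxj1 CRISPR replicate.

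Of 58 neural models, 3 were higher, 4 lower and 51 not called, with 4 and 4 adjusted over the list alone (median 0.2 with camera direction down, adjusted p = 0.971, adjusted p = 0.984 with an estimated correlation). FOXD3 was higher (log2 3.73 ± 0.41), as was a TUBB2B model by a ratio of 29.5 (5.29 to 1170), with -0.55 when multiply matching reads were counted at each model, and GBX2 (-3.72 ± 0.44) and NCAM1 (-1.69 ± 0.36) were lower. Of 32 mesoderm and endoderm models, 4 were lower, 0 higher and 28 not called, with 7 lower and 1 higher adjusted over the list alone (median -0.21, camera adjusted p = 0.0992, adjusted p = 0.568 with an estimated correlation). T was higher with CRISPR by a ratio of 131 (36.3 to 1080) and MYF5 at least 8.37-fold. Both lists shrank without single libraries, the neural list to 4 without either Foxn4 CRISPR replicate, and the mesoderm list to 2 without either Foxj1 CRISPR replicate, 1 without either Foxn4 CRISPR replicate, and 0 and 1 without morpholino replicates 1 and 2. Of 117 motility models, 2 were lower, 0 higher and 115 not called, with 2 and 0 adjusted over the list alone (median -0.54, camera adjusted p = 8.26e-08, adjusted p = 0.757 with an estimated correlation). The transport list had 1 lower and 55 not called, with 1 and 0 adjusted over the list alone (median -0.38, camera adjusted p = 0.00402, adjusted p = 0.784 with an estimated correlation), and the centriole, regulator and Notch lists had 0, 0 and 1 called members, the same adjusted over the list alone. Their medians were -0.31, 0.28 and 0.1, the lowest camera adjusted p was 0.0854 and the lowest adjusted p 0.784 with an estimated correlation.

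Highest over CRISPR were FAM166A, CCDC42 and TMEM88, at least 227, 103 and 95.5 times, GTF2I (log2 8.9 ± 0.78) and CHAC1. FAM166A, CCDC42 and TMEM88 were near 0 with either CRISPR, at up to 0.0723 CPM against 1.52 to 9.01 in the controls. Lowest beside SLC26A4 were RGS2, ratio 143 (39.5 to 1180), PAQR5 (-5.55 ± 0.63) and ANK3 (-5.11 ± 0.76). Next was ATP6V0A4 of the proton pump (-5.0 ± 1.07). PAQR5 rose with either CRISPR, at 79.3 to 130 CPM against up to 1.09 in the controls and 3.87 with the morpholino. In all 505 models were higher and 537 lower, and 4509 had an unadjusted p under 0.05. Of the 32 named models called, 15 and 18 lost their call without Foxn4 CRISPR replicates 1 and 2, 17 and 11 without morpholino replicates 1 and 2, and up to 3 without any other library.

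Against the shared controls, the perturbations moved many of the same models the same way. Foxn4 CRISPR and the morpholino had 2004 models higher and 1532 lower in both, and 34 in opposite directions. Independent lists of these sizes would share 572 and 428. Across models, which are not independent replicates, the correlation of fold changes was 0.72 and the covariance 1.802, against 0.377 and 0.09 in simulations with no effect, which gave 0 shared calls. Foxn4 and Foxj1 CRISPR shared 2127 higher and 1808 lower models with 0 in opposite directions (473 and 420 for independent lists), with a correlation of 0.875 and a covariance of 2.188 (simulated 0.382 and 0.091). Foxj1 CRISPR and the morpholino shared 2833 higher and 2657 lower, with 60 opposite, a correlation of 0.749 and a covariance of 2.198 (simulated 0.384 and 0.09, and 900 and 832 for independent lists). In all 3 comparisons 1832 models rose and 1411 fell, together 3243. Without Foxj1 CRISPR replicate 1 this number was 1912, and without Foxn4 CRISPR replicates 1 and 2 it was 1010 and 1226. In each perturbed library ADA stood at 22.1 CPM or more, against up to 0.0574 in the controls, and AGTR2, MYOT and CAV1 at 0. The shared controls all belong to an earlier study.

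In the authors' deposited table, 1547 models were higher and 1652 lower with Foxj1 CRISPR, and 98.4% of those tested in both were also called here in the same direction. For the morpholino, the authors' deposited table had 1687 higher and 2375 lower, with 94.3% also called. For Foxn4 CRISPR, the authors' deposited table had 1181 higher and 820 lower, with 96.9% also called, and 0 models were called in opposite directions in any of the 3. Motility models called lower in the authors' deposited table numbered 96 of 121 with Foxj1 CRISPR, 41 of 121 with the morpholino and 4 of 120 with Foxn4 CRISPR.

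ChIP-seq showed where Foxn4 bound the genome in caps, alone or with Multicilin, with 1 library each and so no replicate check. Foxn4 peaks lay at the starts of most cilium genes and at FOXJ1 and FOXN4 themselves, but also within 1000 bp of the start of 63.9% of all tested models for Foxn4 alone and 38.9% with Multicilin. The list for Foxn4 alone had 65258 peaks of 340 bp, from 7387992 tags of which 33.51% lay in peaks, and that for Foxn4 with Multicilin had 29673 peaks of 276 bp, from 4911853 tags with 11.86% in peaks. Of the latter, 87.1% (95% interval 86.7 to 87.4) overlapped a peak of the former, and 39.6% (39.2 to 40) the other way round, or 67.3% when the lists were made equal in size by score. Since depth and enrichment differed, the numbers of peaks do not compare the conditions. Peak centres lay within 1000 bp of a gene start for 19.3 and 24.9% of peaks, against 2.3 and 2.5% when the peak centres were shifted by 50000 bp.

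Peaks were found at the starts of all 3 FOXJ1 models, with centres 88, 50 and 76 bp from the start for Foxn4 alone and 121, 31 and 54 bp with Multicilin. Both FOXN4 models had peaks as well, at 248 and 661 bp for Foxn4 alone and 223 and 177 bp with Multicilin. At HYDIN, of the central pair apparatus, on scaffold 15416 the peaks held 284.2 and 173.1 normalized tags, per the deposited lists. The strongest of all peaks at a gene start lay at DYNLL2, a dynein light chain, on scaffold 36586, with 1311.6 and 755.3 normalized tags. At DNAH6, whose RNA was among those that differed most, the nearest peak centres lay 4654 and 4687 bp from the start.

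With Multicilin, 86.3% of the 117 motility models had a peak at the start, against a mean of 61.4% over 10000 random lists matched on expression. For transport the shares were 82.1 against 57.1%, for centrioles 80.7 against 57.2% and for regulators 70.0 against 48.3%, each at or above the 99.0 percentile of the random lists. Notch genes had 46.9 against 31.0%, at the same 99.0 percentile, stress genes 56.4 against 42.2%, at the 98.2 percentile, immune genes 37.8 against 28.0% and cell cycle genes 46.6 against 44.4%. Lists below their random mean were ionocyte (26.0 against 41.6%), secretory (27.6 against 40.3%), p53 (38.5 against 43.0%), epidermal (46.6 against 51.1%), neural (25.9 against 32.0%) and mesoderm (18.8 against 23.4%). Within 5000 bp several of these lay above their random mean, the epidermal list with 82.2 against 63.2%, the neural list with 55.2 against 41.7% and the p53 list with 59 against 53.7%, while the ionocyte list stood at 52.0 against 52.2%. With Foxn4 alone the motility share was 87.2 against 76.8%, the centriole share 94.7 against 74.9% and the ionocyte share 44.0 against 67.8%. For Foxn4 alone the random lists were matched on RNA of caps given Multicilin, not on expression in the caps used for this ChIP. Within 5000 bp the motility share for Foxn4 alone was 93.2 against 90.8%, at the 76.4 percentile, the centriole share 96.5 against 88.6% and the ionocyte share 78.0 against 80.2%. The epidermal and neural shares for Foxn4 alone lay below their random mean within 1000 bp (50.7 against 71.2% and 43.1 against 57.4%) and above it within 5000 bp (94.5 against 84.5% and 84.5 against 69.9%). These figures describe these libraries.

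**Figure D3:**
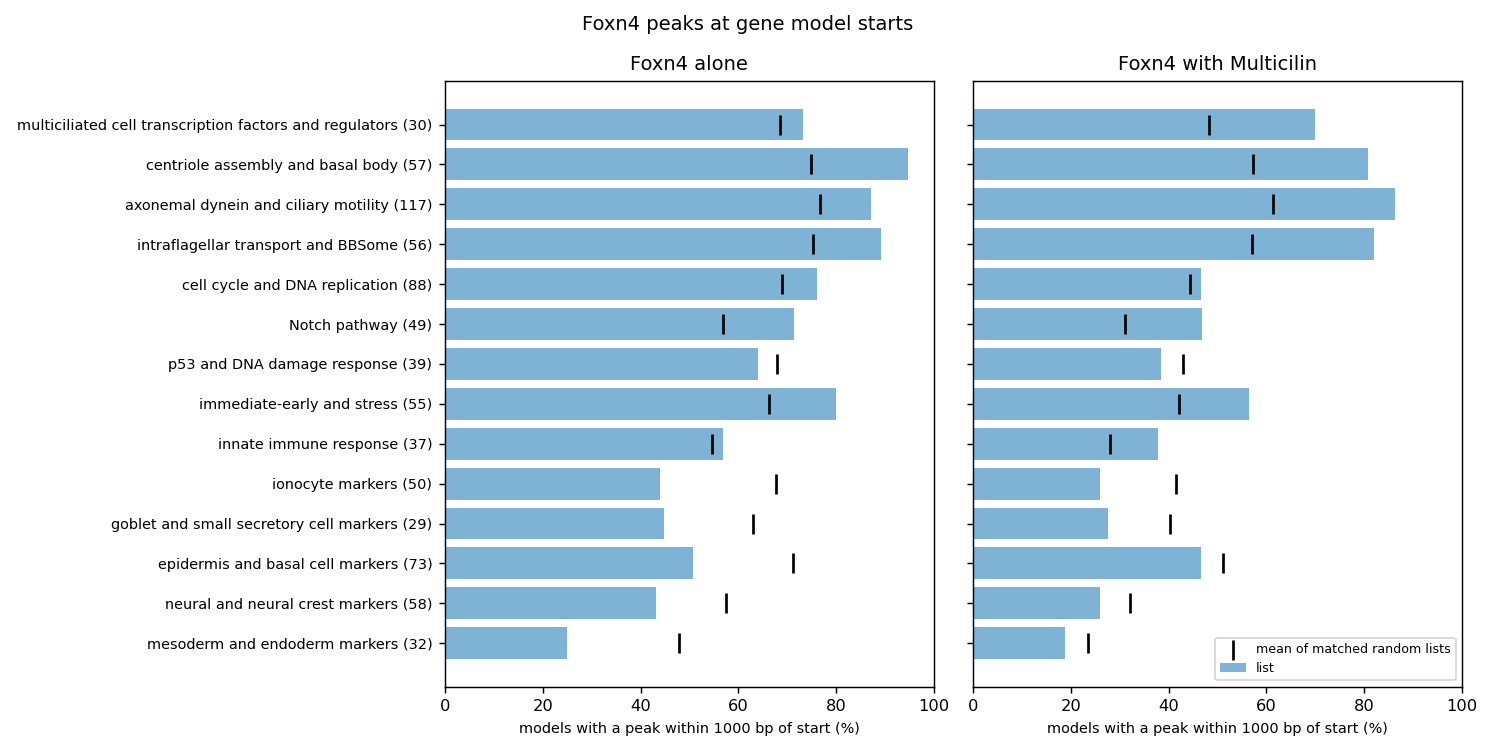
Bars give the percentage of tested models of each list with a Foxn4 peak centre within 1000 bp of the start, for Foxn4 alone (left) and Foxn4 with Multicilin (right); ticks mark the mean of 10000 random lists matched on expression, and brackets give the number of models. With Multicilin the motility list reaches 86.3% against 61.4%, and the ionocyte list 26.0% against 41.6%. Expression was that of RNA libraries from caps given Multicilin, in both panels.

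Peaks were then set against the RNA changes. Of the 272 models higher in Foxn4 CRISPR than in Foxj1 CRISPR, 69.5% had a Foxn4 peak with Multicilin, against 38.4% of models not called, an odds ratio of 2.07 (1.58 to 2.71, adjusted p = 2.37e-07 over 42 tests) at matched expression. With the peaks of Foxn4 alone it was 1.05 (0.79 to 1.4, adjusted p = 0.714). Strata of expression came from caps given Multicilin, so odds ratios for Foxn4 alone are not matched on expression in the caps used. The values 2.07 and 1.05 are therefore not like for like. Models lower in Foxn4 CRISPR than in the control had peaks of Foxn4 with Multicilin less often than uncalled ones, at 0.82 (0.74 to 0.9, adjusted p = 0.000116), and higher models at 0.56 (0.51 to 0.62). With the morpholino the odds ratio was 1.04 (0.97 to 1.13, adjusted p = 0.312) for lower models, or 1.18 (1.09 to 1.27) with a window of 5000 bp, and 0.75 (0.69 to 0.81) for higher models. With Foxj1 CRISPR it was 1.03 (0.96 to 1.12, adjusted p = 0.426) for lower models, or 1.09 (1.01 to 1.18, adjusted p = 0.0333) with a window of 5000 bp, and 0.8 (0.74 to 0.87) for higher models. With the peaks of Foxn4 alone, within 1000 bp, lower models had odds ratios below 1 in all 3 comparisons with the control, at 0.76 (0.7 to 0.82, adjusted p = 2.31e-11) with Foxj1 CRISPR, 0.72 (0.65 to 0.79, adjusted p = 1.7e-10) with Foxn4 CRISPR and 0.86 (0.79 to 0.93, adjusted p = 0.00051) with the morpholino. Within 5000 bp the value for the morpholino was 1.08 (0.98 to 1.2, adjusted p = 0.138). These tests treat gene models as independent.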

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

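The tests of stage in the first and second pattern and of clutches in the third were written down before their results were seen, and the others were chosen after the result was seen. A set of 34 gene models drew attention because the groups differed: they were called in opposite directions with the Foxn4 morpholino and with Foxn4 CRISPR. All 34 were also called between the 2, which their selection made nearly certain and which adds no further evidence. Of these, 26 were lower with CRISPR and higher with the morpholino, such as FAM166A, at 1.84, 1.52 and 4.7 CPM in the controls, 0 in both CRISPR libraries and 19.2 and 46 CPM in the morpholino libraries. CCDC42 stood at 3.62, 2.99 and 2.98 CPM, at 0 in both CRISPR libraries and at 12.8 and 16.9 CPM with the morpholino. In the Foxj1 CRISPR libraries FAM166A stood at 0.0723 and 0 CPM and CCDC42 at 0 in both. The low level of these examples was therefore not particular to Foxn4 CRISPR. The other 8 went the other way, HMX3 and HMX2 among them. By a test of the difference between the groups, 43 motility models were higher in Foxn4 CRISPR than in Foxj1 CRISPR caps, and 13 ionocyte models were lower with the morpholino than with Foxn4 CRISPR.

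The first pattern was the large set of models changed the same way in all 3 comparisons with the re-used controls. Greater depth of the controls is excluded as the cause, since thinning all libraries to the shallowest gave at least 0.92 of the number, and between 2808 and 2830 of the 3243 models were called again in the same direction. A difference between the earlier and the new study cannot be told from a shared effect of the perturbations, because 0 new libraries had Multicilin alone. A younger stage of the new caps could account for part of it: maternal and oocyte transcripts, which decay with age, had medians of 0.78 (0.26 to 1.53), 0.69 (0.07 to 1.01) and 1.26 (0.45 to 2.09), although these intervals are wide and only 9 of the 18 symbols reached 5 CPM in the control. Shared targets of Foxn4 and Foxj1 remain possible as a biological cause and were not separated from these.

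The second pattern was the lower level of motility genes in Foxj1 CRISPR than in Foxn4 CRISPR caps. An offset between studies is excluded by the design, since both groups are new, and the median difference of 1.36 (95% interval 1.21 to 1.55) only restates the pattern. Fewer or less induced multiciliated cells are undecided as a cause. Motility genes differed by 0.93 (0.52 to 1.21) more than early Multicilin-response genes, which differed by 0.43 (0.23 to 0.92). A weaker or later induction could give this gap and is not excluded. The bootstrap intervals of list medians resample members and omit spread between caps. A younger stage of the Foxj1 CRISPR caps is undecided, with a median of 0.27 (0.08 to 0.41) for maternal transcripts. The known role of Foxj1 in switching on motility genes may be the biological cause, with 2 libraries on each side.

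The third pattern was the difference between the morpholino and CRISPR against Foxn4. A depth difference is excluded, since thinning gave at least 0.95 of the number. Of the 1042 models, 908 to 948 were called again in the same direction. A p53 response to the morpholino is undecided, with a median of 0.06 (-0.53 to 0.29), 0 members higher and 3 lower, because the morpholino libraries differed, at -0.12 and 0.77 for the list against 0.34 and 0.48 with CRISPR. Different parents or clutches could account for part of it. Here 32 models were on in both libraries of one set and off in both of the other, against 1 between the CRISPR sets. Against the controls Foxj1 CRISPR, Foxn4 CRISPR and the morpholino had 76, 54 and 69. Single libraries within a group differed at 16 (morpholino) and 14 (Foxn4 CRISPR) models, against 80 to 124 between these groups. A real difference could give such models too. A more complete loss of Foxn4 with the morpholino, or effects of it on other genes, was not tested.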

How the results depend on the processing

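The tests named as added later were chosen after the result was seen, and the cause was not tested unless stated. Of the values for named genes, 4839 kept their direction and side of the threshold, 398 fell short of it, 29 passed it and 8 turned direction, and 123 could not be obtained. Counts of called genes stayed within 1.5 times in 85 cases and moved further in 26, and counts of list members in 921 and 213. Camera results kept their call in 335 cases, lost it in 78 and gained it in 7. Where a group was left with 1 library, that library was assumed to vary like the other groups, and fewer samples gave less power. With every library thinned to the shallowest, Foxj1 CRISPR against the control gave 7207 calls and Foxn4 against Foxj1 CRISPR 314.

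Leaving out single libraries gave from 3431 to 8250 calls for Foxj1 CRISPR against the control, 1213 to 5048 for Foxn4 CRISPR, 5310 to 9008 for the morpholino, 0 to 614 for Foxn4 against Foxj1 CRISPR and 121 to 1868 for the morpholino against Foxn4 CRISPR. Models shared by Foxn4 CRISPR and the morpholino numbered 1027 to 4137, and those shared by the CRISPR groups 1189 to 4586.

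With all matching reads counted at each model, calls numbered 7044 for Foxn4 CRISPR and 3551 for the morpholino against CRISPR, and shared models 5932 for the Foxn4 perturbations and 6282 for the CRISPR groups. Counts summed per symbol, with fewer units tested, gave 2871 for Foxn4 CRISPR, 5658 for the morpholino and 678 for the morpholino against CRISPR. For Foxn4 against Foxj1 CRISPR, DESeq2 gave 739, no filter 429 and only the 2 groups 705. For the morpholino against CRISPR, DESeq2 gave 2174 and length-corrected counts 1737. Of the peaks with Multicilin, 80.8% were shared at reciprocal overlap of 0.5, 85.4% by centres and 67.3% in lists of equal size, against 87.1%. Of the peaks of Foxn4 alone, 67.3% were shared in lists of equal size, against 39.6%.

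With the replicate number as a block, Foxn4 against Foxj1 CRISPR had 0 calls by edgeR, with 2167 at an unadjusted p under 0.05. A block over the 4 CRISPR libraries alone, added later, gave 5473. Same-numbered libraries correlated by -0.142, -0.025 and -0.122 between controls and new groups. The CRISPR groups gave 0.515, and 0.174 and 0.092 with the morpholino. Not all passed 0.1, so numbers were not taken to pair samples, but pairing of CRISPR libraries stays open.

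With all matching reads counted at each model, the direction turned for RBPJ (0.62 with Foxj1 CRISPR, 0.05 with the morpholino), TUBB2B (3.1) and ACTA1 (0.22) with Foxj1 CRISPR, KRT12 (-1.01) with Foxn4 CRISPR and TUBB2B (-0.55) between the morpholino and CRISPR. KRT12 was -1.04 on unique reads. Fitted values for GSX1 with Foxn4 CRISPR ranged from -1.71 without Foxn4 CRISPR replicate 2 to 11.63 without control replicate 1, and neither is a measured fold, since 1 group stood at 0 in each. The cause of the others was not tested.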

Other observations

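The list of maternal transcripts was added after the numbers of changed genes were seen, and before its own values were seen. Genes whose RNA the egg supplies were more often higher than lower in the perturbed caps than in the control. Of 35 models, 13 rose and 1 fell with Foxj1 CRISPR, 11 rose and 0 fell with Foxn4 CRISPR, and 19 rose and 2 fell with the morpholino. BTG4, which takes part in clearing maternal RNA, rose on scaffold 22415 with log2 fold changes of 3.12, 2.28 and 3.11 in this order. ZAR1, an oocyte RNA-binding protein, rose by 2.72, 1.99 and 3.29. TRIM36, a ubiquitin ligase of the egg cortex, rose by 3.3, 2.36 and 4.25 on scaffold 373399, and ZP2, of the egg coat, by 2.83, 2.91 and 3.5 on scaffold 93416. WEE2 fell with Foxj1 CRISPR (-1.6) and the morpholino (-1.24), and LIN28A fell with the morpholino (-1.6).

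The strongest peak of Foxn4 alone lay at positions 1061427 to 1061767 of scaffold 50694, with 2759.9 normalized tags and 116047 bp from the nearest gene start, that of TAF9.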
